A study of Homo sapiens with 8 samples.

How the data were processed

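The series holds 8 RNA-seq libraries of total RNA from the human leukaemia cell lines NB4 and Kasumi-1, 1 per line untreated and 1 each after 6, 12 and 24 h with 40 uM chlorprothixene. Per the labels' protocols, cells grew in serum-supplemented medium, RNA was column-purified and treated with DNase, and libraries were made with an Illumina TruSeq RNA kit; a vehicle, cell numbers and strand-specific preparation are not given in the sources used here. Per the submitters' processing notes, reads were aligned to hg19 with HISAT2 and quantified with StringTie; versions, options and the annotation are not given in the sources used here. Samples were grouped by the cell line and time in their titles.

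Each deposited table lists 57820 gene IDs with gene name, chromosome, strand, start and end. The deposited FPKM values are abundances scaled for transcript length and sequencing depth, the deposited TPM values have the same sum in each library, and the deposited coverage values are the mean read coverage of a gene, per the file headers. Coverage is a signal and was used only to look at depth: its ratio to FPKM, shared by 32.9% to 34.6% of the genes compared in a library, was 9.17, 8.85, 7.08 and 7.79 in NB4 (untreated, 6, 12 and 24 h) and 8.24, 9.83, 9.29 and 7.23 in Kasumi-1. This stands for the aligned bases of a library if FPKM was scaled to all of them. The commonest numbers of aligned bases in low genes were 151 and 302, from which pairs of 151-base reads were inferred. On that basis 1 TPM corresponds to 12.7, 12.0, 9.7 and 11.0 read pairs per kb in NB4 and 11.2, 13.4, 13.3 and 10.5 in Kasumi-1; this is inferred, and no count test was run because the values are not counts. Depth differed by less than 1.5 times between libraries, and values near 0 rest on a handful of read pairs.

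Gene types came from GENCODE 29 by gene ID without version (matched for 91.4% of the IDs), and coordinates only from the deposited tables. Of 55765 symbols, 301 had more than 1 row, which were summed. Y-linked genes, XIST and TSIX (492 in all) were left out. The 14648 genes with a mean of at least 1 TPM over the 8 libraries were tested on log2(TPM + 1), so folds of low genes are understated. No library was identical to another. A gene listed at 0 can be a failed estimate, and the size of a log2 difference from 0 (as for IER5) follows from the pseudocount.

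Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold; tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9. The shared response was the mean of the 3 treated times minus untreated, with cell line as an additive term (3 residual degrees of freedom), so that its p-values measure how alike the 2 lines responded, not the spread of cultures. The line difference came from the same model. The response difference was the product of line and treatment with the times of a line as repeats (4 residual degrees of freedom). Within a line there is no replicate, and genes at least 2-fold changed at all 3 times were counted without a test; 100 simulated sets of unchanged libraries gave the count that arises from a shared untreated library.

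Gene lists were fixed beforehand: FOXO family, FOXO targets, BCL2 family, fusion partner genes, cholesterol synthesis and uptake, fatty acid synthesis, LXR targets, and ATF4 and integrated stress response. Others were endoplasmic reticulum chaperones, lysosome, autophagy, heat shock, NRF2 targets, p53 targets, DNA replication, mitosis, MYC and ribosome biogenesis, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, nuclear oxidative phosphorylation, and hypoxia and glycolysis. The remaining lists were primary granule proteins, myeloid maturation markers, progenitor markers, NF-kB and chemokines, immediate early genes, interferon-stimulated genes, metallothioneins, histones, receptors bound by chlorprothixene, nuclear long noncoding RNAs, and erythroid, lymphoid and epithelial markers. They were tested with limma's camera (preset correlation of 0.01, and again with an estimated correlation) where at least 3 members were tested, adjusted over the 31 such lists. The estimated form rests on the few residual degrees of freedom of the fit, so a call lost there need not come from correlation among genes. The shared response was the contrast fixed for these tests, and the response difference of the lists was tested in addition. Of the 602 distinct members tested, 1 passed the shared test over all genes, and 123 were higher and 80 lower at an unadjusted p under 0.05.

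The rule for named genes was fixed beforehand: up to 10 genes each way for the shared response and the line difference, 5 each way for the response difference, 5 each way within a line by the largest smallest change over the 3 times, with at least 5 TPM in a library (for the shared response in a library of each line). It added every member of the FOXO, BCL2, fusion partner and receptor lists, and up to 4 members of each other list by mean change. For the rules other than the lists, clones, pseudogenes named as such, ribosomal RNAs and small nuclear or nucleolar RNAs did not count. A gene that met the rule is not reported here. List members outside the rule that are named as part of a count over the list alone were chosen after their values were seen.

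Alternatives chosen before the data were examined were a pseudocount of 0.1, no filter and a mean of at least 5 TPM, FPKM, median-centred values, and TPM without mitochondrial and the 10 most abundant genes. Others were eBayes without a trend, no line term, treated against untreated with times as repeats, 1.5-fold and 3-fold rules, Pearson's r, and each library left out. Added after seeing the data were a limma test within each line, leaving out the genes of chromosome 6 from 28 to 34 Mb, and 6 and 12 h only. The test within each line took its spread from both lines together. The code was tested on simulated data with 200 changed genes among 14648. The shared fit called 61% of genes changed 2-fold and 99% of those changed 4-fold, with 7 unchanged genes called. In the data the spread of this fit holds the differences between the lines at each time, and larger mean changes did not pass. CCL3 had a mean log2 change of 5.32 (limma adjusted p = 0.0748) and CCL4 of 4.39 (0.0607). The simulated shares are thus no guide to the power of the shared test here. The line difference called 73% and 99% (15 unchanged called), the response difference 0% and 24% (3 unchanged called), and the within-line test in NB4 27% and 93% (10 unchanged called). Camera called 10 of 10 changed lists and 0 of 10 unchanged lists with either correlation. In the data the estimated form kept 0 of the 15 lists that the preset one called for the shared response. It called 0 of 31 for the response difference, so the simulation is no guide to its power here.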

Results

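Total RNA of 2 human acute myeloid leukaemia cell lines was sequenced without and with chlorprothixene, a thioxanthene antipsychotic that blocks dopamine, serotonin, histamine and muscarinic receptors. NB4 was established from an acute promyelocytic leukaemia and carries the PML-RARA fusion, and Kasumi-1 from a myeloblastic leukaemia with the RUNX1-RUNX1T1 fusion. Each line gave 1 untreated library and 1 library each after 6, 12 and 24 h with 40 uM of the drug, so none of the 8 conditions has a replicate and the values below carry no spread between cultures. The comparisons ask how the transcriptome of each line moved over time, what both lines shared and where they differed. Levels are TPM (abundance scaled to the same total in every library) as deposited, and changes are differences of log2(TPM + 1) from the untreated library of the same line. The untreated libraries are not matched to the times and no vehicle is named, so drug and time in culture are confounded.

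Between 13358 genes (NB4, 6 h) and 14582 genes (Kasumi-1, 6 h) reached 1 TPM in a library. The ratio of coverage to FPKM, from which depth was inferred, lay between 7.08 and 9.83, and on that basis 1 TPM was worth 9.7 to 13.4 read pairs per kb of transcript. Mitochondrially encoded genes took 6.71%, 5.04%, 6.41% and 5.62% of the TPM in NB4 (untreated, 6, 12 and 24 h) and 8.73%, 7.94%, 10.58% and 17.12% in Kasumi-1. The 10 most abundant genes of each library took 6.62% to 7.31% in NB4, and 9.25%, 9.18%, 10.53% and 14.97% in Kasumi-1 in the same order. The median gene moved by at most 0.08 on the log2 scale in any treated library.

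Few single genes moved so alike in both lines that they passed the test of the shared response. FCAR, the Fc receptor for IgA of myeloid cells (chromosome 19, 55385704 to 55401838, hg19), went from 0.826 TPM to 7.38, 8.89 and 4.74 TPM in NB4 and from 9.84 to 38.4, 48.2 and 28.3 TPM in Kasumi-1. HSPA1A, an inducible heat shock protein (chromosome 6, 31783291 to 31785723), went from 0.977 to 12.3, 8.57 and 5.80 TPM in NB4 and from 4.29 to 32.7, 28.3 and 13.7 TPM in Kasumi-1. The mitochondrial glutamine tRNA MT-TQ (chromosome M, 4329 to 4400) stood at 18.0 and 18.2 TPM untreated and reached 174.5 TPM in NB4 and 264.5 TPM in Kasumi-1. The clone-named gene AC020663.1 (chromosome 16, 4853207 to 4854787), named here after its values were seen, went from 5.78 to 78.2 TPM in NB4 at 24 h and from 1.41 to 69.7 TPM in Kasumi-1.

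In the additive limma model these 4 genes rose, with mean log2 changes of 1.96 (SE 0.16, adjusted p = 0.0363) for FCAR, 2.24 (SE 0.18, adjusted p = 0.0363) for HSPA1A, 2.84 (SE 0.26, adjusted p = 0.0443) for MT-TQ and 4.17 (SE 0.28, adjusted p = 0.0259) for AC020663.1. Each was higher in 6 of 6 treated libraries. By limma 0 genes fell, with 1363 genes higher and 1619 lower at an unadjusted p under 0.05. FCAR passed only without NB4 at 24 h or the untreated Kasumi-1 library among the 8 fits that left out 1 library. HSPA1A did not pass without untreated NB4, NB4 at 6 or 12 h, or Kasumi-1 at 6 or 12 h, and MT-TQ did not pass without these or without untreated Kasumi-1. The 4 became 0 with a pseudocount of 0.1, with no filter on low values or with no cell line term, and 1 with FPKM. TPM recomputed without mitochondrial genes and the 10 most abundant genes gave 21 genes higher and 4 lower, genes with a mean of at least 5 TPM gave 21 and 6, and a fit with the times of a line as repeats gave 78 and 55. HSPA1A lies in a stretch of chromosome 6 where many genes are listed at 0 and is nearly identical to HSPA1B (log2 1.93, adjusted p = 0.0694). AC020663.1 lies inside GLYR1 on the same strand, and MT-TQ lies on the strand opposite most mitochondrial transcripts, so the assignment of reads to all 3 is uncertain. The count of 4 became 2 without the untreated NB4 library, 0 without NB4 at 12 h, Kasumi-1 at 6 h or Kasumi-1 at 12 h, and 10 without NB4 at 24 h. It became 12 without Kasumi-1 at 24 h, 43 without the untreated Kasumi-1 library, and 1 without the genes of chromosome 6 from 28 to 34 Mb. The lower count became 3 without NB4 at 24 h and 7 without the untreated Kasumi-1 library.

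At 6, 12 and 24 h taken alone, limma called 0 genes in either direction. At an unadjusted p under 0.05, 919, 1037 and 1224 genes were higher and 879, 1215 and 1512 lower. FCER1G, the gamma chain of Fc receptors, was among the genes nearest to the threshold over all times (mean log2 change 1.81, SE 0.21, adjusted p = 0.0607). At 6 h the count of higher genes was 2 without untreated NB4, 8 without NB4 at 24 h, 13 without untreated Kasumi-1 and 2 without Kasumi-1 at 24 h. At 12 h it was 2 without untreated NB4, 13 without NB4 at 24 h (1 lower), 23 without untreated Kasumi-1 (3 lower), 1 without Kasumi-1 at 12 h and 12 without Kasumi-1 at 24 h (1 lower). At 24 h it was 2 without untreated NB4, NB4 at 6 h or Kasumi-1 at 6 h, 4 without NB4 at 24 h (4 lower) and 20 without untreated Kasumi-1 (3 lower).

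**Figure D1:**
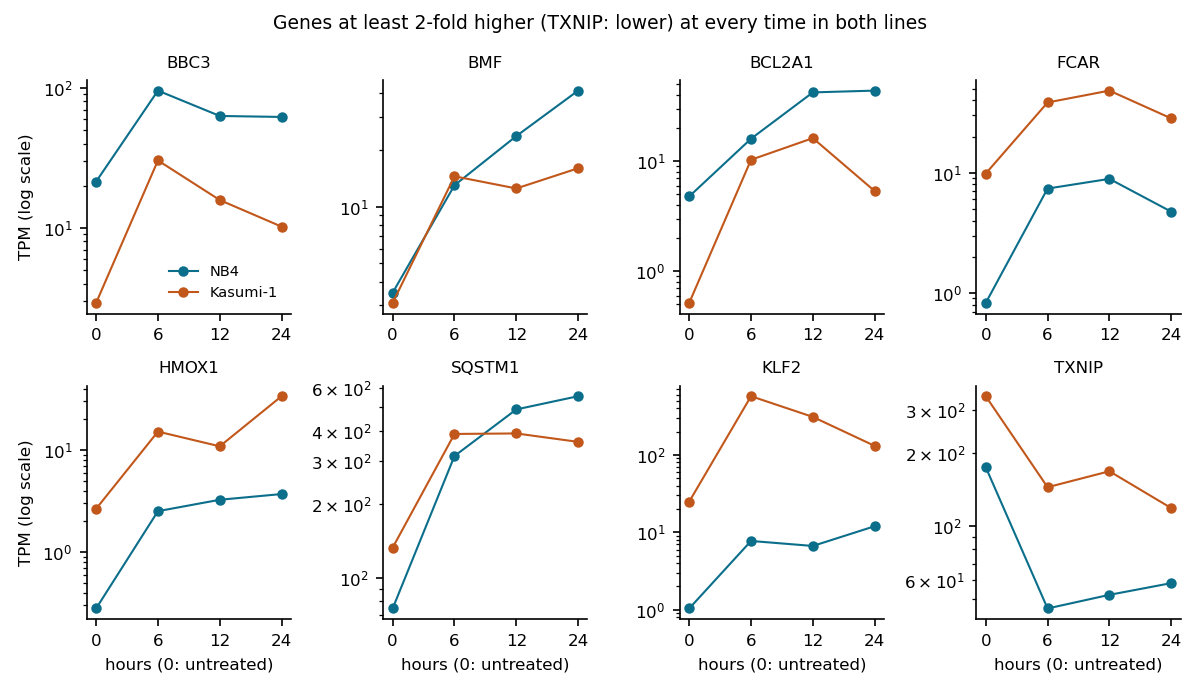
TPM (log axis) of 8 genes in the untreated library and after 6, 12 and 24 h with chlorprothixene, NB4 in teal and Kasumi-1 in orange, 1 library per point; the genes were picked after values were seen. FCAR lay at 4.74 TPM or more in every treated NB4 library against 0.826 TPM untreated, and TXNIP lay below its untreated level in all 6 treated libraries.

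Genes fixed by function beforehand gave a broader picture of what both lines did. Of the cholesterol synthesis and uptake genes, 17 of 24 rose in the shared limma test adjusted over the list alone, and 0 over all genes (18 higher at an unadjusted p under 0.05). Among them were INSIG1, the sterol-regulated retention protein (63.9 to 556.1 TPM in NB4 and 94.9 to 194.5 TPM in Kasumi-1 at 24 h) and SC5D, a late enzyme of the pathway (12.8 to 104.1 and 13.5 to 39.7 TPM). HMGCS1 went from 59.5 to 373.7, 473.2 and 658.0 TPM in NB4 and from 80.6 to 126.8, 79.6 and 212.2 TPM in Kasumi-1, and MSMO1 from 28.3 to 235.2 TPM and from 53.1 to 113.9 TPM at 24 h. In the limma tests within a line described below, 21 of the 24 rose over the list alone in NB4 and 1 in Kasumi-1. Of 11 fatty acid synthesis genes, 6 rose over the list alone, including FASN, ACSS2, FADS2 and ME1. Camera with a preset correlation placed both lists above other genes (adjusted p = 1.3e-10 and 4.7e-04), but not with an estimated correlation (adjusted p = 0.497 and 0.513). CYP51A1, another sterol enzyme, named after its values were seen, was at or under 0.277 TPM in all NB4 libraries and between 95.8 and 218.5 TPM in Kasumi-1.

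Lysosome and autophagy genes rose in part. Of 30 lysosome genes, 4 rose over the list alone: SMPD1, which encodes acid sphingomyelinase, the cholesterol exporters NPC1 and NPC2, and TPP1. NPC2 went from 27.8 to 84.1 TPM in NB4 and from 43.2 to 126.1 TPM in Kasumi-1 at 24 h. Of 23 autophagy genes, SQSTM1, MAP1LC3B, OPTN and TFE3 rose over the list alone. SQSTM1, a cargo receptor, went from 74.8 to 554.9 TPM in NB4 and from 132.8 to 360.5 TPM in Kasumi-1 at 24 h, and TFE3, a transcription factor of lysosomal genes, had a mean log2 change of 1.05 (SE 0.12, limma adjusted p = 0.0607 over all genes). Camera called both lists (adjusted p = 6.3e-05 and 5.7e-04), and neither with an estimated correlation (adjusted p = 0.497 for each). The estimated correlation of the autophagy list was 0.01, the same as the preset one, so the loss of its call need not come from correlation. This was the lowest among the lists called for the shared response, where it reached 0.73 for cholesterol genes. It was 0.18 for lysosome, 0.63 for fatty acid synthesis, 0.63 for DNA replication and 0.62 for NF-kB and chemokine genes. For lists far above 0.01, the preset form can give p-values that are too small. Of 7 targets of the sterol receptor LXR, 0 passed over the list alone (1 higher and 2 lower at an unadjusted p under 0.05 in limma), and camera did not call the list (adjusted p = 0.793).

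The genes of cell death and of stress programmes moved unevenly. Of 15 tested BCL2 family members, BBC3, BMF and BCL2A1 rose over the list alone; the first 2 are pro-apoptotic BH3-only genes and BCL2A1 is anti-apoptotic. BBC3 went from 21.4 to 95.6 TPM in NB4 and from 2.91 to 30.3 TPM in Kasumi-1 at 6 h, BMF reached 41.3 TPM in NB4 and 16.0 TPM in Kasumi-1 at 24 h from 3.50 and 3.09 TPM, and BCL2A1 43.8 and 5.35 TPM from 4.78 and 0.515 TPM. Their mean log2 changes were 1.96 (SE 0.21), 2.17 (SE 0.30) and 2.65 (SE 0.39), with limma adjusted p = 0.0607, 0.0638 and 0.0748 over all genes. MCL1 went from 110.3 to 200.3, 240.8 and 209.9 TPM in NB4, and from 202.8 to 280.7, 246.8 and 186.0 TPM in Kasumi-1. The mean log2 changes of BCL2, BCL2L1, BCL2L11, BID, BIK, BAX and BAK1 lay between -0.23 and 0.13 and those of BCL2L2, PMAIP1, BAD and BOK between 0.34 and 0.74. Some of these means join opposite changes: 0.49 in NB4 and -0.48 in Kasumi-1 for BID, 0.59 and -0.65 for BIK, 0.13 and -0.58 for BCL2L1, and -0.38 and 0.23 for BCL2. For BCL2L2 they were 1.18 and 0.30, and for BOK -0.03 and 1.18. HRK was at or below 0.0517 TPM in every library. Camera called the family upward (adjusted p = 0.00174), but not with an estimated correlation (adjusted p = 0.497).

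The FOXO transcription factor genes had mean log2 changes of -0.08 for FOXO1, -0.01 for FOXO3 and 0.46 for FOXO4, and FOXO6 stayed at or below 0.869 TPM. FOXO3B, which the family list also held but whose gene type is processed pseudogene, had a mean log2 change of 0.02. FOXO4 went from 6.84 to 7.63, 8.31 and 10.4 TPM in NB4 and from 7.33 to 8.38, 13.8 and 13.6 TPM in Kasumi-1, and FOXO1 from 1.72 to 0.973 TPM in NB4 at 24 h. None of the 4 tested passed over the list alone (1 higher at an unadjusted p under 0.05 in limma), and camera did not call them (adjusted p = 0.692). Of 23 FOXO target genes, BBC3, BCL6, CDKN1A, TNFSF10, KLF6, CCNG2 and TXNIP passed over the list alone, 5 of them higher and 2 lower. TXNIP, an inhibitor of thioredoxin, fell by 1.49 on the log2 scale over both lines (SE 0.18, adjusted p = 0.0607 over all genes), from 174.1 to 45.8 TPM in NB4 and from 340.7 to 144.1 TPM in Kasumi-1 at 6 h. Camera did not call the targets (adjusted p = 0.134). Of 19 p53 targets, CDKN1A, BBC3, TNFRSF10B and BTG2 rose and FDXR and AEN fell over the list alone (camera adjusted p = 0.0861). CDKN1A, the cell cycle inhibitor p21, went from 0.344 to 7.88, 23.5 and 30.1 TPM in NB4 and from 8.81 to 37.3, 49.0 and 12.4 TPM in Kasumi-1.

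Of 16 NRF2 targets of the oxidant response, HMOX1, NQO1, ME1 and PGD rose over the list alone (camera adjusted p = 0.00315, or 0.497 with an estimated correlation), and HMOX1, haem oxygenase, went from 0.280 to 3.71 TPM in NB4 and from 2.66 to 33.8 TPM in Kasumi-1 at 24 h. Of 17 heat shock genes, HSPA1A passed over all genes, HSPA1A, HSPA1B and DNAJB1 rose and HSPD1 fell over the list alone, and camera did not call the list (adjusted p = 0.131). Of 24 endoplasmic reticulum chaperones and unfolded protein response genes, DNAJB9 and SYVN1 rose over the list alone (camera adjusted p = 0.0326, or 0.819 with an estimated correlation). The list's median change was 0.33, 0.33 and 0.29 in NB4 and 0.09, 0.09 and -0.49 in Kasumi-1 at 6, 12 and 24 h. The medians of the lines thus had opposite signs at 24 h. Of 29 ATF4 and integrated stress response genes, 0 passed over the list alone (3 higher and 3 lower at an unadjusted p under 0.05 in limma; camera adjusted p = 0.854). Their median change was 0.89, 0.28 and -0.27 in Kasumi-1 and 0.05, -0.30 and -0.50 in NB4 at 6, 12 and 24 h.

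Of 32 DNA replication and G1/S genes, 17 fell over the list alone and 0 over all genes (20 lower at an unadjusted p under 0.05 in limma). MCM2, a subunit of the replicative helicase, stood at 236.2 TPM untreated and 92.2 TPM at 24 h in Kasumi-1, and at 323.7 and 225.4 TPM in NB4. UNG, a uracil DNA glycosylase, went from 272.9 to 76.6 TPM in Kasumi-1 and from 222.7 to 155.7 TPM in NB4 at 24 h. The list's median change was -0.80, -0.86 and -1.02 in Kasumi-1 and -0.20, -0.37 and -0.09 in NB4 at 6, 12 and 24 h. Of 26 MYC and ribosome biogenesis genes, 16 fell over the list alone, MYC itself among them, from 86.2 to 32.2 TPM in NB4 and from 41.0 to 33.5 TPM in Kasumi-1 at 6 h. Of 35 nuclear genes of oxidative phosphorylation, NDUFS1, SDHA, UQCRFS1 and ATP5A1 fell over the list alone, with SDHA at 313.6 and 178.7 TPM in NB4 and 154.7 and 77.5 TPM in Kasumi-1, untreated and at 24 h. Camera called the 3 lists downward (adjusted p = 2.9e-09, 1.7e-09 and 2.1e-07), and none with an estimated correlation (adjusted p = 0.497 for each).

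Mitosis and G2/M genes (30 tested, 0 past over the list alone, 0 at an unadjusted p under 0.05 in limma) and the 13 mitochondrially encoded mRNAs (0 past, 1 lower at an unadjusted p under 0.05) showed no shared change by camera (adjusted p = 0.945 for both). The median change of the mitochondrial mRNAs was 0.93 in Kasumi-1 at 24 h, the library with a mitochondrial share of 17.12%, and between -0.47 and 0.13 in the other treated libraries. Of 61 cytosolic ribosomal protein genes, 0 passed over the list alone (2 higher at an unadjusted p under 0.05 in limma), while camera called the list upward with a median of 0.12 (adjusted p = 0.00325, or 0.819 with an estimated correlation). The 13 replication-dependent histone genes (0 past, 2 lower at an unadjusted p under 0.05; camera adjusted p = 0.321) and the 21 hypoxia and glycolysis genes (0 past, 4 higher and 4 lower at an unadjusted p under 0.05; camera adjusted p = 0.924) were not called either. NDRG1, a stress-induced gene of the last list, went from 3.63 to 82.9, 34.9 and 24.7 TPM in Kasumi-1. Median and mean differed in sign for the hypoxia list (-0.06 and 0.14, camera up), the LXR targets (0.10 and -0.05, up), the ATF4 genes (-0.01 and 0.06, up), the mitochondrial mRNAs (0.04 and -0.04, down) and the lymphoid markers (-0.27 and 0.06, up).

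Myeloid identity genes moved in both directions. Of 24 tested myeloid maturation markers, 7 rose over the list alone (ITGAM, ITGAX, FCGR1A, CD68, C5AR1, TYROBP and FCER1G) and S100A9 fell. FCER1G, the shared gamma chain of Fc receptors, went from 33.7 to 151.1 TPM in NB4 and from 2.36 to 14.2 TPM in Kasumi-1 at 24 h, and ITGAX, which encodes CD11c, from 1.67 to 27.9 and from 1.15 to 10.2 TPM. Camera called the list upward (adjusted p = 7.2e-04), but not with an estimated correlation (adjusted p = 0.497). Of 12 primary granule genes, the proteases PRTN3 and CTSG and the ribonuclease RNASE2 fell over the list alone (camera adjusted p = 0.201); CTSG went from 464.3 to 95.1 TPM in NB4 and from 11.6 to 6.08 TPM in Kasumi-1 at 12 h, after 19.0 TPM in Kasumi-1 at 6 h. Of 13 progenitor markers, the repressor GFI1 fell over the list alone (177.5 to 73.4 TPM in NB4 and 324.6 to 177.1 TPM in Kasumi-1 at 24 h; camera adjusted p = 0.131). In Kasumi-1, KIT went from 449.8 to 72.5, 115.1 and 191.6 TPM and CD34 from 111.8 to 18.3, 36.5 and 57.5 TPM.

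Neither line showed a called change in the genes of its fusion. PML, RARA, RUNX1 and RUNX1T1 had mean log2 changes of -0.30, 0.10, -0.22 and -0.18 in the shared fit, with 0 past over the list alone and 0 at an unadjusted p under 0.05 in limma (camera adjusted p = 0.515). RUNX1T1 was between 58.0 and 92.5 TPM in Kasumi-1 and at or under 0.0476 TPM in NB4; gene-level values do not separate fusion transcripts from the normal ones. Most receptors bound by chlorprothixene were at or near 0: of 19 genes, HRH1 alone reached a mean of 1 TPM, at 0.359 TPM untreated and 8.21, 1.42 and 10.1 TPM in NB4 (shared adjusted p = 0.310). HTR7 and CHRM5 reached 2.25 and 1.67 TPM in NB4 and HTR6 0.911 TPM in Kasumi-1. The levels of DRD4, HTR2B, CHRM2 and CHRM4 stayed at or under 0.609 TPM and those of DRD2, HTR2A, CHRM3, ADRA1B and ADRA1D at or under 0.0799 TPM. DRD1, DRD3, DRD5, HTR2C, CHRM1 and ADRA1A were listed at 0 in all 8 libraries.

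The NF-kB and chemokine genes had a median shared change of 1.66 and the immediate early genes of 1.09. The median of the NF-kB list was 2.26, 2.76 and 2.70 in NB4 and 0.28, 0.27 and -0.17 in Kasumi-1 at 6, 12 and 24 h, so most of the shared median came from NB4. Of 21 NF-kB and chemokine genes, 8 rose in the shared test over the list alone (NFKBIA, IL8, CCL3, CCL4, CCL4L2, RELB, NFKB2 and TRAF1), and 0 over all genes (12 higher at an unadjusted p under 0.05 in limma). CCL3 went from 0.312 to 56.1, 104.1 and 166.9 TPM in NB4 and from 0.119 to 52.6, 32.2 and 6.14 TPM in Kasumi-1; CCL3, CCL4 and CCL4L2 have near-identical copies and their values are uncertain. Of 24 immediate early genes, 9 rose over the list alone (FOSL1, JUN, JUNB, JUND, IER5, NR4A1, KLF2, ZFP36 and BTG2), IER5 with an untreated value of 0 in Kasumi-1. KLF2 went from 24.9 to 572.7 TPM in Kasumi-1 at 6 h and was at 130.7 TPM at 24 h, and in NB4 it went from 1.04 to 12.0 TPM at 24 h. The median of the immediate early list was 1.53, 0.81 and 0.03 in Kasumi-1 and 1.19, 1.58 and 1.76 in NB4 at 6, 12 and 24 h. Of 22 interferon-stimulated genes, IRF7 and IRF9 rose over the list alone. Camera called the 3 lists upward (adjusted p = 3.8e-07, 3.0e-06 and 0.0439), and none with an estimated correlation (adjusted p = 0.497, 0.497 and 0.747). The call of the interferon list was also lost with no filter on low values, a mean of at least 5 TPM, FPKM, and TPM without mitochondrial and top 10 genes. The 5 tested metallothioneins were not called (0 past over the list alone, 0 at an unadjusted p under 0.05 in limma; camera adjusted p = 0.945).

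Markers of other cells and of RNA quality were looked at in the same way. Of the nuclear noncoding RNAs, MALAT1 rose over the list alone (2 tested, 0 over all genes), from 9.59 to 21.6 TPM in NB4 and from 23.1 to 116.5 TPM in Kasumi-1 at 24 h. NEAT1 went from 6.13 to 88.9, 103.3 and 92.7 TPM in NB4 and from 75.8 to 24.3, 112.7 and 150.7 TPM in Kasumi-1. Of 8 lymphoid markers, NKG7, a granule membrane gene, rose and CD4, which monocytic cells also carry, fell over the list alone (0 over all genes in limma, 1 higher and 1 lower at an unadjusted p under 0.05; camera adjusted p = 0.955). Of 4 erythroid and megakaryocyte markers (camera adjusted p = 0.779) and 2 epithelial and fibroblast markers, 0 passed in limma and 0 had an unadjusted p under 0.05.

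**Figure D2:**
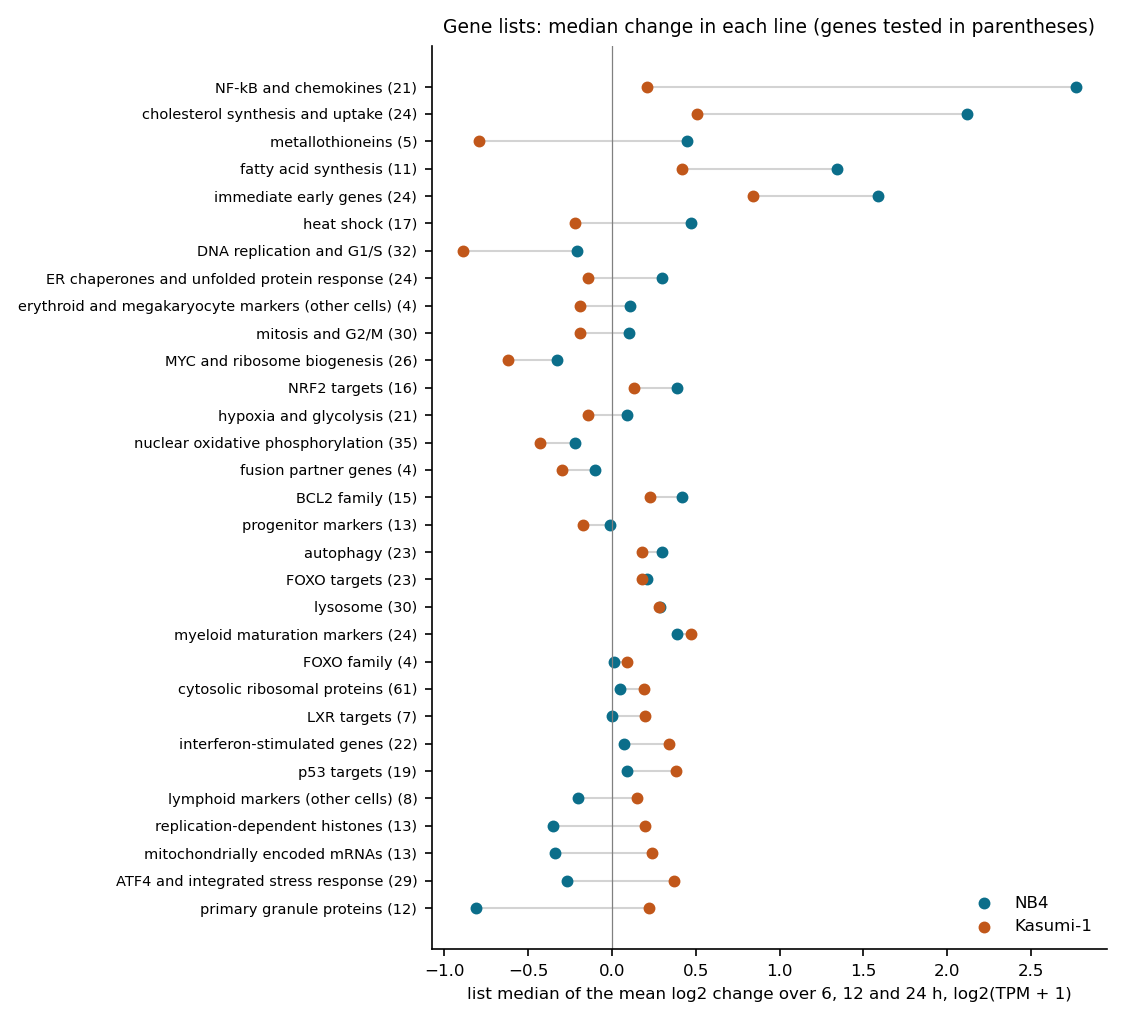
Median over the members of each of 31 gene lists of the mean log2 change over the 3 times, on the log2(TPM + 1) scale, for NB4 (teal) and Kasumi-1 (orange). The NF-kB and cholesterol lists stood at 2.77 and 2.12 in NB4 against 0.21 and 0.51 in Kasumi-1, and the DNA replication list at -0.21 against -0.89.

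In NB4, 297 genes were at least 2-fold higher and 103 at least 2-fold lower at all 3 times, a rule of size without a test. Among the genes with the largest changes, CXCL10, an interferon-inducible chemokine, went from 0.731 TPM to 183.1, 244.7 and 122.2 TPM and the adhesion receptor ICAM1 from 6.58 to 339.8, 494.0 and 378.7 TPM. IL8 went from 4.24 to 187.8, 276.9 and 134.4 TPM, and CCL3 as above. ABCA1, a cholesterol exporter, went from 12.5 to 0.438, 0.619 and 0.595 TPM, and SERPINB10, a serpin, from 10.7 to 0.235 TPM at 24 h. RPS18 went from 211.5 to 26.3 TPM at 24 h, the tubulin gene TUBA4A from 141.0 to 15.7 TPM at 12 h, and the read-through gene PTGES3L-AARSD1 from 24.3 to 0.102 TPM at 6 h.

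A limma test of the change within the line was chosen after the values were seen. It took the 3 times as repeats and assumed that the single untreated library varies like them. Its spread was pooled over both lines, which can understate the spread of a gene near 0 in the other line, as SERPINB10 and ABCA1 were in Kasumi-1. The test called 91 genes higher and 26 lower in NB4, of which 87 and 23 were among those that met the rule of size. It called CXCL10 (adjusted p = 0.00161), ICAM1 (5.6e-04), CCL3 (0.0468), IL8 (0.0492), ABCA1 (0.00234), SERPINB10 (0.0116), RPS18 (0.0318) and PTGES3L-AARSD1 (0.0116), and not TUBA4A (0.106). By this test 17 of 24 cholesterol genes and 12 of 21 NF-kB and chemokine genes rose over all genes. Simulated unchanged libraries met the rule of size for 26.3 genes higher and 25.8 lower on average, since the 3 differences share 1 untreated library. RPS18 lies in a stretch of chromosome 6 where many genes are listed at 0, and PTGES3L-AARSD1 overlaps AARSD1 on the same strand.

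In Kasumi-1, 275 genes were at least 2-fold higher and 96 at least 2-fold lower at all 3 times. ANXA1, a phospholipid-binding anti-inflammatory protein, went from 0.602 TPM to 28.1, 69.7 and 19.4 TPM, ARC, an immediate early gene, from 0.626 to 16.9, 13.2 and 12.7 TPM, and the calcium-binding S100A6 from 0.337 to 10.4, 15.8 and 9.18 TPM. IER5, an immediate early gene (chromosome 1, 181057638 to 181059977), was listed at 0 untreated and at 39.1, 40.3 and 31.7 TPM in the treated libraries, and the read-through gene SENP3-EIF4A1 was at 1.39 TPM untreated and 72.9 TPM at 12 h. SNX22, a sorting nexin, went from 17.6 to 0.326, 0.175 and 1.81 TPM and the chemokine CXCL2 from 51.5 to 8.25, 6.98 and 6.50 TPM. The phosphatase PDXP went from 56.6 to 5.50 TPM at 24 h, the arrestin-domain gene ARRDC3 from 86.8 to 16.8, 16.5 and 14.8 TPM, and the read-through CORO7-PAM16 from 21.2 to 0.232 TPM at 24 h.

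The limma test within the line, on the same assumption and with the spread pooled over both lines, called 30 genes higher and 16 lower in Kasumi-1, all of which met the rule of size. It called IER5 (adjusted p = 1.1e-04), SENP3-EIF4A1 (0.00989), ANXA1 (0.0360), ARC (0.00989), SNX22 (0.0375), CXCL2 (0.0246), PDXP (0.0159) and ARRDC3 (0.00989), and not S100A6 (0.0727) or CORO7-PAM16 (0.0629). UNG (0.0360) and MCM2 (0.0443) fell among the DNA replication genes. SNX22 and ARC stayed at or under 0.105 and 0.287 TPM in NB4, so the pooled spread can understate theirs. A gene listed at 0, as IER5 was, can be a failed estimate, and the size of a change from it follows from the pseudocount. PDXP overlaps SH3BP1 and the read-through genes overlap their neighbours on the same strand, so their values are uncertain.

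**Figure D3:**
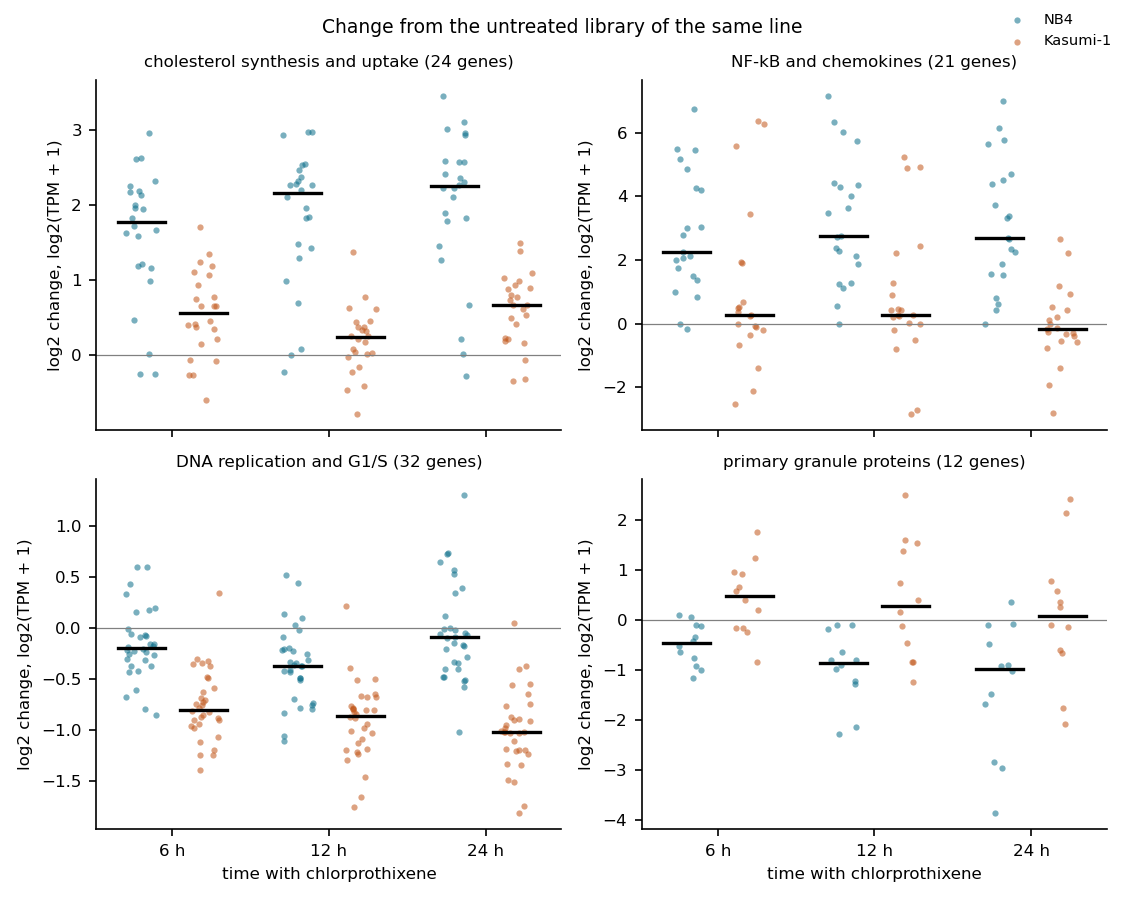
Log2 change of each gene from the untreated library of its line at 6, 12 and 24 h for 4 lists (24 cholesterol, 21 NF-kB and chemokine, 32 DNA replication and 12 primary granule genes), NB4 in teal, Kasumi-1 in orange, the black bar at the list median; the lists were picked after values were seen. The cholesterol medians were 1.78, 2.15 and 2.25 in NB4 and 0.55, 0.23 and 0.67 in Kasumi-1.

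The changes of the lines were weakly related across genes. Spearman's rho was 0.253 for the correlation of the 2 lines' changes at 6 h, 0.305 for the correlation of the 2 lines' changes at 12 h and 0.322 for the correlation of the 2 lines' changes at 24 h, and genes are not independent replicates. Of the genes at least 2-fold higher at all 3 times, 41 were in both lines, where independent lists of these sizes would share 5.58 if every gene were equally likely to pass. Among the 41 were BBC3, BMF, BCL2A1, FCAR, HMOX1, KLF2, NR4A1, SQSTM1, SC5D and CCL3. They also held mitochondrial tRNAs, small nucleolar RNAs and clone-named genes. The 5 genes lower in both, where 0.675 would be shared, were TXNIP, CORO7-PAM16 and, named after their values were seen, ARRDC4, LRRC20 and RP11-480I12.5. GPR84, a receptor for medium-chain fatty acids, was higher in NB4 (23.6 to 86.2 TPM at 24 h) and lower in Kasumi-1 (8.92 TPM at 6 h and 4.25 TPM at 24 h). CCPG1 was lower in NB4 (94.2 to 36.9 TPM) and higher in Kasumi-1 (4.59 to 42.3 TPM). Both were named after their values were seen. The lines share no library, so shared controls do not enter these overlaps.

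The response of few genes was called different between the lines. In the limma model of line, treatment and their product, 13 genes changed more positively in NB4 and 6 in Kasumi-1 (933 and 618 at an unadjusted p under 0.05). Among the largest in NB4 were CXCL10 (difference of log2 changes 6.75, SE 0.65, adjusted p = 0.0187), ICAM1 (5.82, SE 0.42, adjusted p = 0.00669), TNFAIP3 (5.14, SE 0.49, adjusted p = 0.0187), and the monocyte chemokine CCL2 (4.16, SE 0.38, adjusted p = 0.0187). TNFAIP3, an NF-kB feedback inhibitor, went from 8.58 to 183.7, 184.9 and 197.3 TPM in NB4, and was at 86.5 TPM untreated and 32.5, 49.3 and 69.3 TPM in Kasumi-1. On the other side stood IER5 (adjusted p = 0.00669), SLX1A (-3.15, SE 0.37, adjusted p = 0.0343), ABCA1 (-3.15, SE 0.33, adjusted p = 0.0222), SYTL1, a vesicle transport gene (-3.11, SE 0.37, adjusted p = 0.0343), and ARC (-3.07, SE 0.39, adjusted p = 0.0482). SYTL1 was at 71.2 TPM untreated and 31.1, 37.9 and 51.5 TPM in NB4, and went from 15.5 to 83.7, 79.2 and 73.3 TPM in Kasumi-1. SLX1A has a near-identical copy, SLX1B, and IER5 rests on an untreated value of 0, so that the size of its difference follows from the pseudocount. ABCA1 was at or under 0.0280 TPM and CCL2 at or under 0.287 TPM in Kasumi-1, and ARC at or under 0.287 TPM in NB4. The spread was pooled over both lines, which can understate it for such genes. Without Kasumi-1 at 12 h none of these 9 genes passed, and ICAM1 and IER5 passed without any other treated library. CXCL10 was also lost without NB4 at 12 h or Kasumi-1 at 6 h, and TNFAIP3 and CCL2 without NB4 at 12 or 24 h. ABCA1 was lost without NB4 at 12 or 24 h or Kasumi-1 at 6 h, SYTL1 without NB4 at 12 h or Kasumi-1 at 6 or 24 h. SLX1A was lost without all but Kasumi-1 at 24 h, and ARC without any one of the 6.

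By list, in tests that were not among those fixed beforehand, 14 of 21 NF-kB and chemokine genes and 19 of 24 cholesterol genes changed more positively in NB4 when adjusted over the list alone, and 6 and 0 did over all genes. Their median differences were 2.05 and 1.41. Of 32 DNA replication genes 8 did so (median 0.63), and of 12 primary granule genes 4 changed more positively in Kasumi-1 (AZU1, RNASE3, CST7 and SRGN; median -1.27), the last 2 lists with 0 over all genes. Camera called these 4 lists (adjusted p = 7.1e-17, 7.0e-16, 2.8e-10 and 4.6e-06), and none with an estimated correlation (adjusted p = 0.548, 0.632, 0.632 and 0.632). Each untreated library is single and was assumed to vary like the treated ones. The counts of response difference genes more positive in NB4 and response difference genes more positive in Kasumi-1 (13 and 6) became 14 and 12 in TPM without mitochondrial and top 10 genes and 272 and 256 without a filter on low values. Leaving out NB4 at 12 h gave 1 and 2, NB4 at 24 h 3 and 2, Kasumi-1 at 6 h 5 and 1, Kasumi-1 at 12 h 0 and 0, and Kasumi-1 at 24 h 17 and 14.

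Between the lines themselves, 4036 genes were higher in NB4 and 4077 in Kasumi-1 (limma with time as a block, 4 libraries per line). NB4 held more MMP9, a gelatinase of neutrophil granules (log2 difference 8.44, SE 0.77, adjusted p = 1.4e-04), IGFBP2 (8.33, SE 0.14, adjusted p = 6.3e-07), the homeobox genes RHOXF2B (adjusted p = 1.1e-06) and RHOXF2 (6.44), which are near-identical copies so that their split is uncertain. It also held more of the histidine decarboxylase HDC (7.71), the intermediate filament VIM (7.32), CES1 (6.64), MX2 (6.61), SLFN11 (6.41) and the eosinophil peroxidase EPX (6.25). Kasumi-1 held more of the neutrophil elastase ELANE (-9.04, SE 0.26, adjusted p = 1.7e-06), APP (-8.54, SE 0.13, adjusted p = 6.3e-07), C1QTNF4 (-8.13), CTHRC1 (-8.12), SERPINB6 (-7.80), HLA-B (-7.71), ITM2A (-7.39), RHOB (-7.37), SPINT2 (-7.29) and the stem cell factor receptor KIT (-7.21). MMP9 went from 43.6 to 1579.1 TPM in NB4 at 24 h and stayed at or under 0.321 TPM in Kasumi-1. The 4 libraries of a line are different times and treatments, not replicate cultures. HLA-B lies in the stretch of chromosome 6 where many genes are listed at 0.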

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

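The tests of scaling and of untreated levels for the cholesterol genes, the count over other groupings of the libraries and the comparisons of gene lists between the lines were chosen only after the results were seen, while the comparison of the response between the lines gene by gene was chosen before the data were examined.

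The response to chlorprothixene differed between NB4 and Kasumi-1 in limma for 12 genes named in the text. The change in NB4 less that in Kasumi-1 (log2) was 6.75 for CXCL10, 5.82 for ICAM1, 5.14 for TNFAIP3, 4.16 for CCL2, 3.58 for CXCL2, 3.03 for PDXP and 2.72 for ARRDC3. It was -3.07 for ARC, -3.11 for SYTL1, -3.15 for ABCA1, -3.15 for SLX1A and -4.50 for IER5. The value for IER5 rests on 0 TPM in untreated Kasumi-1, so that its size follows from the pseudocount and is not comparable with the others. CXCL2, ARRDC3 and PDXP differed mostly through lower levels in Kasumi-1 with treatment, CXCL2 going from 51.5 to 8.25, 6.98 and 6.50 TPM, and from 1.05 to 2.69, 3.82 and 2.16 TPM in NB4. By size alone, 28 genes (CXCL2 among them) moved in opposite directions by at least 1.5-fold at every time, 16 of them higher in NB4 and 12 higher in Kasumi-1, a difference that was not tested for them as a group.

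Camera with a preset correlation called 15 of 31 lists as different between the lines, and 0 with an estimated correlation (adjusted p between 0.548 and 0.668 for these 15). The median difference (NB4 less Kasumi-1, log2) was 2.05 for NF-kB and chemokine genes, 1.41 for cholesterol genes, 1.32 for metallothioneins, and 0.66 for heat shock genes. It was 0.63 for DNA replication genes, 0.59 for fatty acid synthesis genes, 0.40 for endoplasmic reticulum chaperones, 0.31 for mitosis genes and 0.16 for nuclear genes of oxidative phosphorylation. It was -0.17 for cytosolic ribosomal proteins, -0.47 for LXR targets, -0.58 for ATF4 genes, -0.63 for histones, -0.88 for mitochondrially encoded mRNAs and -1.27 for primary granule genes.

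Cholesterol genes were higher with treatment in NB4 by more than in Kasumi-1, with INSIG1 at 556.1 TPM in NB4 and 194.5 TPM in Kasumi-1 at 24 h, and the list medians differed by 1.61. Under 3 other scalings of the libraries the difference was at least 1.51. Under each scaling the median gene moved by at most 0.08 in any treated library, so these scalings could hardly have removed it. The difference did not depend on which of them was used, and no more is concluded from them. The list stood lower in untreated NB4 than in untreated Kasumi-1 (median -0.80, 1 of 24 members higher in NB4) and higher with treatment (0.76, 18 of 24), which argues against a difference in the untreated level alone. A stronger sterol response of NB4 may be the source, as a hypothesis drawn from these same libraries and not itself tested. Each untreated library is single, and a chance state of that culture stays open.

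The difference between the lines themselves called 8113 genes. Of the 8 groupings of 4 libraries against 4 with 1 library of each time on either side, 1, the real one, called as many, and the highest other called 0. Every other grouping puts libraries of both lines on each side, so the line difference enters its residual spread. A count near 0 was to be foreseen for them, and no conclusion is drawn from it. The number of such groupings is too small for a share under 0.05. Groupings outside these 8, which put both libraries of at least 2 times on the same side, were left out of this count. Those that were run each called 0, and they too mix the lines on both sides.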

How the results depend on the processing

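Leaving out chromosome 6 from 28 to 34 Mb, the limma test within a line and 6 and 12 h only were alternatives chosen after seeing the data; the others were chosen before. The fits without 1 library assume that a lone library varies like the others. The cause of a change was not tested unless stated.

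The shared response genes higher (4) became 0 with a pseudocount of 0.1, 0 with no filter on low values, 21 with a mean of at least 5 TPM, where fewer genes are tested, and 1 with FPKM. They became 21 in TPM without mitochondrial and top 10 genes, 1 without the genes of chromosome 6, 0 with no cell line term and 78 with the times of a line as repeats. Leaving out 1 library gave 0 to 43. The shared response genes lower (0) became 6 with a mean of at least 5 TPM, 4 in TPM without mitochondrial and top 10 genes and 55 with times as repeats, and 0 to 7 without 1 library. For the shared response at 6 h genes higher (0), the values were 2 with a mean of at least 5 TPM, 1 with FPKM and 3 without mitochondrial and top 10 genes, and 0 to 13 without 1 library. For the shared response at 12 h genes higher (0), they were 1 with FPKM, 4 without mitochondrial and top 10 genes and 0 to 23 without 1 library, and 0 to 3 for those lower. For the shared response at 24 h genes higher (0), they were 1 with FPKM and 0 to 20 without 1 library, and 0 to 4 for those lower.

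The response difference genes more positive in NB4 (13) became 272 with no filter on low values, and 0 to 17 without 1 treated library. The response difference genes more positive in Kasumi-1 (6) became 256 with no filter, 12 without mitochondrial and top 10 genes, and 0 to 14 without 1 treated library. An untreated library cannot be left out of this fit, so how these counts depend on the single untreated libraries was not tested. The line difference genes higher in NB4 (4036) and the line difference genes higher in Kasumi-1 (4077) stayed within 1.5 times under every alternative run, with 3031 to 4054 and 3334 to 3865 without 1 library.

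For the NB4 genes at least 2-fold higher at every time (297) and the NB4 genes at least 2-fold lower at every time (103), a pseudocount of 0.1 gave 535 and 187, a rule of 1.5-fold 821 and 493, a rule of 3-fold 117 and 17, and limma within the line 91 and 26. A mean of at least 5 TPM gave 60 lower. For the Kasumi-1 genes at least 2-fold higher at every time (275) and the Kasumi-1 genes at least 2-fold lower at every time (96), these gave 535 and 157, 804 and 717, 78 and 21, and 30 and 16. A mean of at least 5 TPM gave 62 lower, FPKM 177 and 59, and 6 and 12 h only 497 and 194. A rule of another size counts other genes by construction.

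The correlations between the lines moved by less than 0.1 under the alternatives run. Of the values for lists with the preset correlation, 210 kept their side of the threshold and 4 lost it, all of interferon-stimulated genes (medians 0.24, 0.31, 0.25 and 0.27 with no filter, a mean of at least 5 TPM, FPKM and without mitochondrial and top 10 genes). The estimated correlation is not among these values. With it, 0 of the 15 lists called for the shared response kept their call. Of the values for named genes, 2888 were the same, 76 lost and 45 gained a call, and 26 without a test moved by more than 0.58. None reversed, and 43 uncalled values changed sign. A gene uncalled in both fits also counted as the same, so the 2888 do not measure how stable the called genes were. Depth limits genes near 1 TPM, where 9.7 to 13.4 read pairs per kb stand behind a value.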

Other observations

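The tests of mitochondrial RNA and of genes listed at 0 were chosen only after the results were seen.

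Mitochondrial RNA was high in Kasumi-1 at 24 h, with 12 of 13 mRNAs above the untreated library and a median log2 change of 0.93. The total mitochondrial share was 1.96 times that of the untreated library, which argues against reads only divided differently between neighbouring mitochondrial genes. The values of this library did not rise evenly: the SD of the 13 log2 changes was 0.77, against 0.33 to 0.65 in the other treated libraries, with MT-ATP6 going from 2703.8 to 17025.2 TPM and MT-CO1 from 10302.4 to 7626.1 TPM. Some mitochondrial RNAs had already fallen at 6 h, before the share rose, such as MT-TA (748.5 to 278.2 TPM, and 608.3 TPM at 24 h). Whether an even rise came on top of such changes stays open, since single libraries give no spread to judge it by. MT-CO1 and MT-TA were named after their values were seen. A real rise, a loss of other RNA or a difference in RNA preparation of this library cannot be told apart.

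Of 195 protein-coding genes on chromosome 6 from 28 to 34 Mb, 93 (47.7%) were listed at 0 in all 8 libraries, against 5.4% and 7.3% in the flanks and 16.3% of all protein-coding genes. Of 7 genes of that region in families of basic cell machinery (such as LSM2, GTF2H4, VPS52 and proteasome subunits), 6 (85.7%) were at 0, against 1 of 176 (0.6%) elsewhere. This argues against silence in these cells for such genes, and was not tested for the other genes of the region. The families were taken by gene name, and the proteasome subunits were PSMB8 and PSMB9, which not every cell needs. Reads shared with other haplotype copies of the region in a reference are a candidate cause that stays open, since a chromosome 17 region with such copies had 3 of 14 genes at 0 (21.4%). No other biological explanation was tested.

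At 0 in 1 library and at least 10 TPM in the other 7 were 4 genes, named after their values were seen: NSFP1 in NB4 at 12 h, IER5 in untreated Kasumi-1, CTD-2369P2.12 in Kasumi-1 at 12 h and SNORA18 in Kasumi-1 at 24 h.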
